A study of Orbilia oligospora with 9 samples.

How the data were processed

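Total RNA from hyphae of Orbilia oligospora (also called Arthrobotrys oligospora, a fungus that catches nematodes with adhesive networks) was sequenced as standard Illumina libraries. The cultures had grown for 5 days at 28 °C on TYGA (tryptone, yeast extract and glucose agar). The 9 libraries fall into 3 groups of 3, WT, Aomdv1 mutant and Aovps1 mutant. Their batch tag holds only the culture day, which all 9 share, and no processing batch is given. The study calls the libraries biological replicates without saying whether each came from its own plate, so the p-values measure the spread between these samples. Sample labels speak of a knockdown, while the study design speaks of deletion mutants.

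The authors deposited one table of FPKM (fragments scaled to gene length and to the number of fragments counted in the library), rounded to 2 decimals. The aligner and the counting program are not given in the sources used here, and neither are the fragment counts. The table holds 12901 loci, of which 11144 carry a locus tag, with coordinates equal to those of the RefSeq assembly of this species, and 1757 do not. Functions are those of the table's own annotation columns (Swiss-Prot and Pfam hits, KEGG orthologs and maps, GO terms). Some KEGG ortholog names contradict the protein hits of the same gene, so lists built from them hold odd members. No identical pair of libraries was found (0 pairs), and the table holds 0 columns of other samples.

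The depth was estimated from the step size of the FPKM values of loci spanning less than 700 bp, where 1 fragment moves the value most. This gave 15850000 to 19300000 fragments per library. With the estimate, 68 to 79.6% of the values lay within 0.1 of a whole number of fragments. Gene spans, which include introns, served as lengths, because transcript lengths are not in the table. At the median gene span of 1362 bp an FPKM of 1 stands for 21.6 to 26.3 fragments. The estimate was tested on simulated tables with depths inside the range searched, where its error was 0%. Those tables were made with the gene spans that the estimate uses and with depths among the values searched. The test therefore could not show the error that comes from unknown transcript lengths. A true depth outside the range searched would not have been found. For library 3 labelled Aomdv1 mutant the estimate rested on 157 values, against 428 to 517 in the other libraries.

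Values were analysed as log2(FPKM + 1). Loci at FPKM 1 or more in at least 3 libraries were kept, which left 10318. All 9 libraries went into 1 linear model with limma 3.58.1 in R 4.3.3 (limma-trend, two-sided moderated test, no term for the replicate number), and adjusted p-values are Benjamini-Hochberg values over the 10318 loci with a threshold of 0.05. An exact permutation test of 3 against 3 libraries cannot give a p-value under 0.1. On simulated data with 200 changed genes, the procedure recovered 0 to 3% of genes changed by 1 on the log2 scale and 51 to 63% of genes changed by 2, with 2 to 4 false calls per comparison. Smaller changes can therefore go uncalled.

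36 gene lists were set from KEGG maps and from keywords in the annotation, for mitochondrial, metabolic, secretory, developmental and housekeeping functions. Each list was compared with all other tested genes by limma's camera with a preset correlation of 0.01 and again with an estimated one, adjusted over the 36 lists. For each list the members past the threshold were counted after adjustment over all tested loci and after adjustment over the list alone. KEGG maps and GO terms with 5 to 500 tested genes (111 and 2358 terms) were tested for enrichment with one-sided Fisher exact tests, separately for genes that rose and fell, against 2865 and 5215 annotated tested genes. GO text of 1292 loci was not usable and was left out.

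Genes are named by a rule: the targeted genes, the 10 rising and 10 falling genes with the largest log2 fold change per mutant, up to 2 risen and 2 fallen members per list described (smallest adjusted p), and the 5 in each direction with the largest smaller change among genes called in both mutants. Apart from the targeted genes, each had to be past the threshold. The genes with the largest changes, per mutant and in both, also needed all 3 mutant libraries on one side of all 3 WT libraries. They further needed a mean FPKM of at least 5 in 1 group and an annotated function. List members were chosen without these conditions. Partner genes of the fission machinery, the 10 genes and 1 neighbour of the arthrosporol cluster, calnexin, members of gene runs and phosphate genes outside this rule were chosen after their values were seen. The comparisons, tests, lists and naming rule were chosen before the data were examined.

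Alternatives were a pseudocount of 0.1, no filter, a filter at a mean FPKM of 5, median-ratio and quantile scaling of the FPKM values, a replicate block, a fit of only the 2 groups compared, an estimated correlation in camera, and leaving out each library in turn. Added after the data were seen were array weights, voom on approximate fragment numbers, leaving out both libraries that stand apart, keyword lists without KEGG ortholog names, and both mutants together against WT. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.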

Results

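Transcript levels were measured by RNA-seq in hyphae of the nematode-trapping fungus Orbilia oligospora grown for 5 days on TYGA, in 3 WT libraries, 3 libraries labelled Aomdv1 mutant and 3 labelled Aovps1 mutant. The estimated depth was 17200000 to 19150000 fragments per WT library, 15850000 to 17350000 per library labelled Aomdv1 mutant and 18100000 to 19300000 per library labelled Aovps1 mutant. Across genes, log2 values correlated at 0.98 to 0.991 among the libraries labelled Aovps1 mutant, at 0.896 to 0.981 among WT libraries and at 0.863 to 0.961 among those labelled Aomdv1 mutant. Between WT and mutant libraries the correlation was 0.791 to 0.892. Between the libraries labelled Aomdv1 mutant and those labelled Aovps1 mutant it was 0.859 to 0.976. That range reaches above and below the range among the libraries labelled Aomdv1 mutant, so this measure does not set the mutant labels apart. The 10 most abundant transcripts took 15.6 to 24.1% of the summed FPKM.

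The study asks what the loss of Mdv1, an adaptor that recruits dynamin to mitochondria, and of the dynamin-related protein Vps1 does to mitochondrial division, mitophagy, spore formation, trap formation and energy metabolism. Transcripts of both targeted genes remained present in the libraries labelled as their own mutants, so these libraries are named by label throughout. The MDV1 gene AOL_s00097g206 (NW_011645654.1, 709346 to 711512, minus strand) stood at 121.18 ± 10.51 FPKM in WT (SD, n = 3), at 109.08 ± 23.50 in the libraries labelled Aomdv1 mutant and at 123.36 ± 22.62 in those labelled Aovps1 mutant. Its log2 fold change in the libraries labelled Aomdv1 mutant was -0.17 (95% interval -0.78 to 0.44, adjusted p = 0.768). The VPS1 gene AOL_s00007g394 (NW_011645564.1, 1420575 to 1423280, plus strand) had 87.06 ± 16.70 FPKM in WT, 44.01 ± 9.95 in the libraries labelled Aomdv1 mutant and 37.94 ± 13.39 in those labelled Aovps1 mutant. VPS1 fell by 1.23 on the log2 scale in the libraries labelled Aovps1 mutant (95% interval -2 to -0.46, adjusted p = 0.0421), leaving 43.6% of the WT mean. That call was lost without any one of the 6 libraries compared. The adjusted p was 0.129, 0.091 and 0.0508 without WT libraries 1, 2 and 3, and 0.0897, 0.159 and 0.0781 without libraries 1, 2 and 3 labelled Aovps1 mutant. In the libraries labelled Aomdv1 mutant VPS1 was at 50.6% of the WT mean (log2 fold change -0.97, adjusted p = 0.117), and its difference between the mutants was not called (-0.26, 95% interval -1.03 to 0.52, adjusted p = 0.79).

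**Figure D1:**
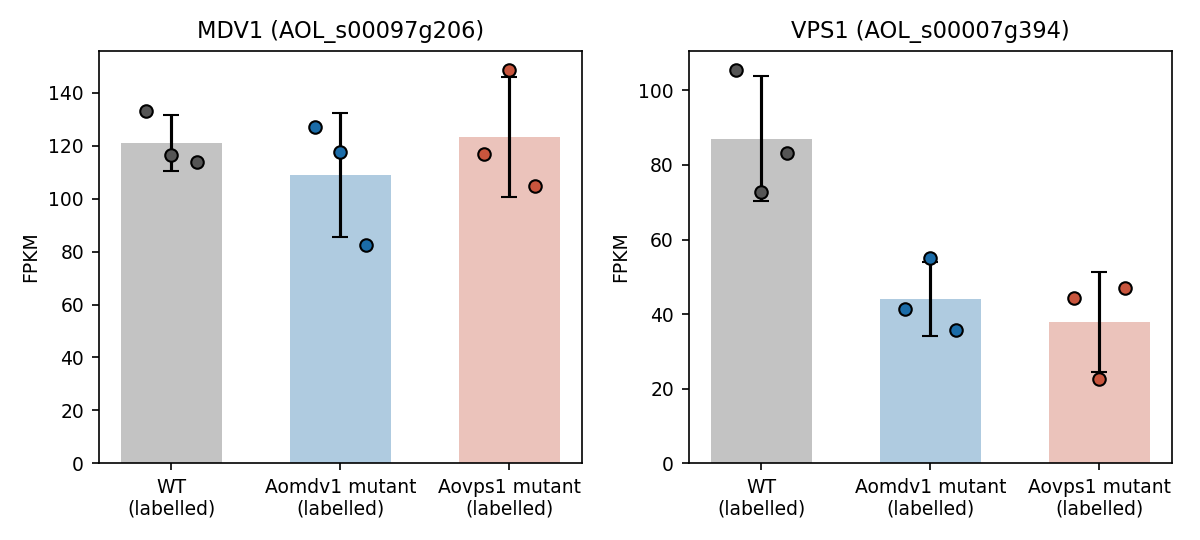
FPKM (y axis) of the MDV1 gene AOL_s00097g206 and the VPS1 gene AOL_s00007g394 in the 3 labelled groups; bars are means, error bars SD and points the 3 libraries of each group. MDV1 lies between 82.46 and 148.53 FPKM in all 9 libraries, and VPS1 between 22.55 and 55.05 FPKM in the 6 mutant libraries against 72.7 to 105.38 in WT.

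The partner genes DNM1, FIS1, FZO1 and MGM1 of mitochondrial fission and fusion did not pass the threshold in either mutant. The dynamin gene DNM1 (AOL_s00078g290) had mean FPKM values of 55.6 in WT, 51.46 in the libraries labelled Aomdv1 mutant and 65.14 in those labelled Aovps1 mutant (adjusted p = 0.831 and 0.659). The membrane anchor gene FIS1 (AOL_s00109g118) had means of 103.3, 137.0 and 124.1 in the same order (adjusted p = 0.505 and 0.568). The fusion genes FZO1 (AOL_s00054g413; 112.45 ± 50.90, 72.88 ± 42.33 and 81.05 ± 6.81, adjusted p = 0.488 and 0.708) and MGM1 (AOL_s00215g191; means 43.69, 48.39 and 49.33, adjusted p = 0.817 and 0.695) were not called either. Of the 26 tested genes on the list for mitochondrial fission and fusion, 2 rose and 1 fell in the libraries labelled Aomdv1 mutant. In those labelled Aovps1 mutant 3 rose and 2 fell, a balance that either scaling turned to 2 and 2. The numbers were the same when adjusted over the list alone. Without members that enter only by a KEGG ortholog name, 15 genes remained, of which 1 rose and 0 fell in the libraries labelled Aomdv1 mutant and 1 rose and 1 fell in those labelled Aovps1 mutant. The list as a whole was not shifted (camera adjusted p = 0.704 and 0.729). Its clearest riser was the fission-process gene MTP18 (AOL_s00079g30), at 20.79 ± 8.03 FPKM in WT, 71.36 ± 19.54 in the libraries labelled Aomdv1 mutant (log2 fold change 1.77, adjusted p = 0.00841, and 0.0518 when only those 2 groups were fitted) and 88.95 ± 1.95 in those labelled Aovps1 mutant (2.12, adjusted p = 0.00297).

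In the libraries labelled Aomdv1 mutant, 18 of 42 proteasome genes rose, as did 8 of 13 genes listed for the arthrosporol cluster, which makes polyketide metabolites from 6-methylsalicylic acid. As sets, both were called as higher with a preset correlation but not with an estimated one (adjusted p = 0.673). Single genes for a hydrophobin, lectins, chitin-binding proteins and the uptake of phosphate, copper and methionine stood lower. No shift of mitophagy genes was detected. A shift of autophagy genes upward was called, but lost with an estimated correlation (adjusted p = 0.673), with quantile scaling (0.0767) and without WT library 3 (0.103) or library 2 labelled Aomdv1 mutant (0.166).

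Among genes with an annotated function, the largest rise was that of an RTA1-like membrane protein gene, AOL_s00076g487 (NW_011645633.1, 1712997 to 1714178), from 0.187 ± 0.17 FPKM in WT to 8734 ± 1440 in the libraries labelled Aomdv1 mutant (log2 fold change 12.84, adjusted p = 1.3e-09). A second RTA1-like gene, AOL_s00054g302, rose from 1.09 ± 0.261 to 580.2 ± 55.2 FPKM (8.12, adjusted p = 2e-07). Further risers were an FAD-dependent monooxygenase (AOL_s00215g259, 8.38, adjusted p = 5.75e-08), a phospholipase A2 (AOL_s00081g9, 7.94, adjusted p = 2.3e-05), the small heat shock protein HSP16 (AOL_s00097g499, 6.51, adjusted p = 8.78e-07) and an endoglucanase (AOL_s00110g290, 6.08, adjusted p = 3.89e-06). The others among the 10 largest were a cupin protein (AOL_s00004g217, 6.29), an FAD-binding protein (AOL_s00080g374, 5.97), a zinc-binding dehydrogenase (AOL_s00054g672, 5.87) and AOL_s00043g814 (5.73), with adjusted p between 1.04e-06 and 6e-05. Each of these genes had all 3 mutant libraries above all 3 WT libraries.

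The deepest fall among annotated genes was that of a hydrophobin gene, AOL_s00006g570. It codes for a small secreted protein of the kind that coats aerial hyphae and spores. Its level went from 1677 ± 259 FPKM in WT to 1.03 ± 0.895 in the libraries labelled Aomdv1 mutant (-9.79, adjusted p = 3.75e-07). A mannose-binding lectin gene, AOL_s00006g511, fell by 8.14 on the log2 scale (adjusted p = 0.00185, and 0.0503 with voom), from WT values of 82.81, 271.81 and 5066 FPKM. The phosphate permease pho-4 (AOL_s00169g251) fell from 1721 ± 1069 to 12.43 ± 11.98 FPKM (-7.24, adjusted p = 0.000106). Further uptake and phosphate genes that fell were the copper transporter CTR3 (AOL_s00078g476, -5.46, adjusted p = 0.00211), a methionine permease (AOL_s00007g56, -5.09, adjusted p = 6.27e-06) and an alkaline phosphatase (AOL_s00215g838, -4.95, adjusted p = 0.00279). A phytase (AOL_s00169g232, -4.92, adjusted p = 0.000239) and a transporter of the major facilitator superfamily (MFS; AOL_s00076g462, -4.90, adjusted p = 0.00107) fell as well. An elongation factor 2-like gene (AOL_s00210g187, -6.05, adjusted p = 4.15e-06) and an Hsp70 gene (AOL_s00170g37, -5.09, adjusted p = 1.69e-05) completed the 10.

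Among the lists, the proteasome stood out: 18 of its 42 tested genes rose and 0 fell (27 rose when adjusted over the list alone; 17 rose under either scaling). Its median log2 fold change was 0.88, above that of other genes (camera adjusted p = 8.96e-12, but adjusted p = 0.673 with an estimated correlation). The alpha-2 subunit gene AOL_s00081g362 went from 147.1 ± 25.8 to 498.9 ± 78.1 FPKM (1.76, adjusted p = 0.00143) and the assembly chaperone p27 gene AOL_s00193g76 from a mean of 50.11 to 163.97 (1.69, adjusted p = 0.00198). All 11 tested genes of the GO term for the proteasome core complex rose (Fisher adjusted p = 5.44e-11). On the arthrosporol list 8 of 13 genes rose and 1 fell (10 and 1 over the list alone), a camera adjusted p of 6e-06 (adjusted p = 0.673 with an estimated correlation). Its polyketide synthase gene AOL_s00215g283, annotated as 6-methylsalicylic acid synthase, rose from 13.80 ± 6.85 to 217.8 ± 109.3 FPKM (3.87, SE 0.453, adjusted p = 0.000432), and AOL_s00215g274 at the other end of the cluster from 158.1 ± 46.1 to 875.0 ± 110.6 (2.49, adjusted p = 0.000383). The lists for secondary metabolism and cytochrome P450, from which arthrosporol genes were not removed, were not shifted as sets (camera adjusted p = 0.128 and 0.0619). Of 21 secondary metabolism genes 6 rose and 1 fell (8 and 3 over the list alone; 4 and 3 with quantile scaling), and of 34 cytochrome P450 genes 6 rose and 2 fell (9 and 3 over the list alone). Among the risers was an ophiobolin F synthase-like gene (AOL_s00081g1, 4.19, adjusted p = 0.000189).

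**Figure D2:**
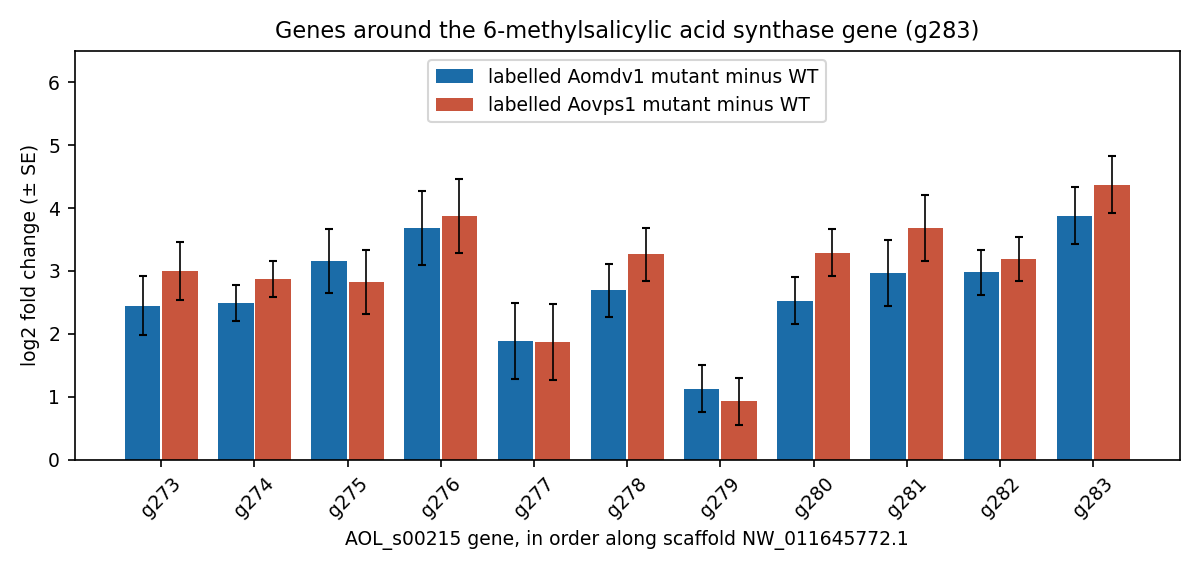
Log2 fold change against WT (y axis, error bars SE) of the genes AOL_s00215g273 to g283 in order along scaffold NW_011645772.1 (867239 to 900192), for the libraries labelled Aomdv1 mutant and Aovps1 mutant. All 11 genes stand above 0 in both; of the 10 cluster genes g274 to g283, g277 (adjusted p = 0.081 and 0.0659) and g279 (adjusted p = 0.0977 and 0.13) did not pass the threshold.

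Smaller shifts upward were called by camera for lists of degradation, traffic and mitochondria, all of them lost with an estimated correlation (adjusted p = 0.673, and 0.683 for mitochondrial import and ribosome). Of 102 autophagy genes 7 rose and 1 fell (4 and 1 with median-ratio and 5 and 0 with quantile scaling; camera adjusted p = 0.0165), with the conjugating enzyme gene Atg3 (AOL_s00078g458) going from 29.36 ± 8.53 to 109.4 ± 7.21 FPKM (1.90, adjusted p = 0.00165). Of 49 mitophagy genes 2 rose and 0 fell, 1 and 0 over the list alone, with no shift of the set (camera adjusted p = 0.587). Of 107 endocytosis genes 10 rose and 2 fell (camera adjusted p = 0.0186), led by an ARF GTPase gene (AOL_s00097g286, 3.89, adjusted p = 0.00202). Of 112 genes for protein processing in the endoplasmic reticulum (ER) 6 rose and 2 fell (3 and 2 with median-ratio and 4 and 2 with quantile scaling; camera adjusted p = 0.013). The lists for oxidative phosphorylation (97 genes, median log2 fold change 0.40) and for mitochondrial import and ribosome (101 genes, 0.41) were both shifted up (camera adjusted p = 0.00274 for each). Few single mitochondrial genes passed. For oxidative phosphorylation 3 rose and 1 fell, where median-ratio scaling turned the balance to 1 up and 2 down, and for import and ribosome 0 passed with limma. Of 72 genes of oxidative stress defence 9 rose and 1 fell (camera adjusted p = 0.0464), among them catalase B (AOL_s00076g488, 0.253 ± 0.156 to 37.69 ± 17.80 FPKM, 4.85, adjusted p = 3.18e-05), the neighbour of the RTA1-like gene AOL_s00076g487. Adjusted over the list alone, the counts were 7 and 1 for autophagy, 14 and 3 for endocytosis, 5 and 1 for ER processing, 1 and 1 for oxidative phosphorylation and 9 and 1 for stress defence.

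Lists of the cell surface and of uptake were called as lower by camera, each lost with an estimated correlation (adjusted p = 0.673). Of 82 genes for adhesion, lectin and CFEM proteins 8 rose and 14 fell (camera adjusted p = 0.00657), and of 192 genes for chitin and cell wall 11 rose and 22 fell (camera adjusted p = 0.0186). A LysM gene (AOL_s00006g493) fell from 86.81 ± 25.06 to 2.14 ± 0.507 FPKM (-4.77, adjusted p = 1.89e-05), and an endoglucanase-5 gene (AOL_s00210g380) from 32.25 ± 3.67 to a mean of 0.73 (-4.27, adjusted p = 2.74e-05). A fucose-binding lectin gene (AOL_s00188g331), at 8.48 ± 3.57 FPKM in WT, was listed at 0 in all 3 libraries labelled Aomdv1 mutant. MFS and sugar transporters (9 rose and 15 fell of 122, camera adjusted p = 0.0364) and nitrogen and amino acid uptake (3 and 9 of 65, camera adjusted p = 0.0446) were also lower. Within the latter the nitrate reductase gene AOL_s00210g163 rose from 3.37 ± 1.73 to 33.75 ± 6.03 FPKM (3.06, adjusted p = 0.000516). Over the lists alone the counts were 9 and 18 for adhesion, 12 and 24 for chitin and cell wall, 13 and 19 for MFS and 6 and 15 for nitrogen. GO terms enriched among genes that fell included the extracellular region (38 of 255, 9.88 expected, adjusted p = 4.21e-10) and chitin binding (8 of 17, adjusted p = 9.37e-05).

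On the list for conidiation and velvet regulators 1 of 35 genes rose and 2 fell (1 and 1 over the list alone; camera adjusted p = 0.0757). The riser was fluG (AOL_s00043g361), from 3.72 ± 1.82 to 16.43 ± 2.20 FPKM (1.96, adjusted p = 0.00693), and the hydrophobin AOL_s00006g570 was a faller. Of 27 secreted peptidases 4 rose and 5 fell (5 and 7 over the list alone; camera adjusted p = 0.111). A cuticle-degrading protease gene (AOL_s00075g8), of the class used against nematode cuticle, fell from 18.77 ± 8.51 to 1.17 ± 0.543 FPKM (-3.14, adjusted p = 0.000578), while a subtilisin-like protease gene (AOL_s00097g479) rose from a mean of 0.04 to 6.88 (2.90, adjusted p = 0.000126). In central carbon metabolism the gluconeogenic gene for phosphoenolpyruvate carboxykinase (AOL_s00004g362) fell from 1970 ± 460 to 389.7 ± 234.1 FPKM (-2.48, adjusted p = 0.0079). The lists for glycolysis and gluconeogenesis (6 rose and 3 fell of 74, 3 and 3 with quantile scaling; camera adjusted p = 0.863) and the TCA cycle (1 and 1 of 32, 0.175) were not shifted.

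In all, 1015 genes passed the threshold, 580 up and 435 down, of which 993 changed at least 2-fold. At an unadjusted p under 0.05 there were 2356, and in 2280 (22.1%, against 10% by chance) the 3 libraries of each group did not overlap. The rising share of 57.1% became 52.9% (559 and 498) with quantile and 45.2% (463 and 561) with median-ratio scaling. It was 70.9% (987 and 405) without WT library 3. Without WT library 1 the count was 627, and without WT library 2 it was 515. A fit of only the 2 groups compared, whose spread leaves out the libraries labelled Aovps1 mutant, gave 528. Of the 12 list calls, 0 were made with an estimated correlation (adjusted p = 0.673 with an estimated correlation, 0.683 for mitochondrial import and ribosome), and with quantile scaling the proteasome, arthrosporol, adhesion and chitin lists remained.

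Only the proteasome and arthrosporol list calls held without each of the 6 libraries in turn. Without library 3 labelled Aomdv1 mutant the adjusted p was 0.267 for oxidative phosphorylation, 0.146 for mitochondrial import and ribosome, 0.0796 for adhesion, 0.146 for chitin and cell wall, 0.291 for oxidative stress defence, 0.121 for MFS and 0.141 for nitrogen. Without WT library 3 it was 0.103 for autophagy, 0.182 for endocytosis, 0.118 for ER processing, 0.0966 for chitin and for mitochondrial import, 0.12 for MFS and 0.103 for nitrogen. Without library 2 labelled Aomdv1 mutant it was 0.166 for autophagy and 0.168 for endocytosis, and without library 1 of that label 0.0509 for nitrogen. Without WT library 2 it was 0.051 for chitin, 0.0597 for stress defence, 0.0684 for MFS and 0.0646 for nitrogen, and without WT library 1 it was 0.173 for stress defence.

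In the libraries labelled Aovps1 mutant, 23 of 42 proteasome genes and 8 of 13 genes listed for the arthrosporol cluster rose, and the same hydrophobin, lectin, phosphate, copper and methionine genes stood far below it. Sets of the proteasome, arthrosporol, autophagy and protein processing in the ER were called as higher, each lost with an estimated correlation (adjusted p = 0.946), and autophagy also without WT library 3 (0.0542). Lists of mitochondrial division, mitophagy and respiration were not shifted as sets.

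The RTA1-like gene AOL_s00076g487 again rose most among annotated genes, to 7226 ± 886 FPKM (log2 fold change 12.57, adjusted p = 1.61e-09). It was followed by the FAD-dependent monooxygenase AOL_s00215g259 (8.01, adjusted p = 9.1e-08), the second RTA1-like gene AOL_s00054g302 (7.37, adjusted p = 3.95e-07), the phospholipase A2 AOL_s00081g9 (6.80, adjusted p = 7.29e-05) and the endoglucanase AOL_s00110g290 (6.34, adjusted p = 4.09e-06). A beta-lactamase-like gene (AOL_s00140g35) was among the 10 largest, at 6.55 in WT and a mean of 333.6 FPKM (5.49, adjusted p = 1.82e-05). The hydrophobin AOL_s00006g570 fell to 0.17 ± 0.2 FPKM (-10.49, adjusted p = 2.5e-07), the pho-4 permease AOL_s00169g251 to 3.66 ± 1.71 (-8.40, adjusted p = 3.41e-05) and the mannose-binding lectin AOL_s00006g511 to 1.43 ± 1.09 (-7.75, adjusted p = 0.00234). A lectin gene of the fungal fruit body type (AOL_s00080g288) went from 9771 ± 5542 to 130.3 ± 33.8 FPKM (-6.08, adjusted p = 1.17e-05), and a serine protease inhibitor gene (AOL_s00054g904) from 306.6 ± 229.3 to 1.20 ± 0.739 (-6.73, adjusted p = 0.000236). AOL_s00215g68 (-5.76, adjusted p = 2.88e-05) and a GLEYA-domain adhesin gene (AOL_s00083g117, -5.29, adjusted p = 0.000504) were further fallers.

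Of the 42 proteasome genes 23 rose and 0 fell (32 over the list alone; 20 rose under quantile and 9 under median-ratio scaling; camera adjusted p = 1.8e-08, but adjusted p = 0.946 with an estimated correlation). The proteasome map was enriched among risers (23 found, 3.75 expected, Fisher adjusted p = 3.1e-12). The alpha-2 subunit gene AOL_s00081g362 stood at 488.9 ± 26.5 FPKM (1.74, adjusted p = 0.00148) and the regulator PI31 gene AOL_s00097g163 went from a mean of 26.01 to 125.5 (2.25, adjusted p = 0.00265). The arthrosporol list had 8 risers and 1 faller of 13 (10 and 1 over the list alone; camera adjusted p = 4.43e-05, and 0.946 with an estimated correlation), with the synthase AOL_s00215g283 at 289.5 ± 83.2 FPKM (4.37, adjusted p = 0.000184) and AOL_s00215g274 at 1146 ± 240 (2.87, adjusted p = 0.000143). The list's faller in both mutants was a cytochrome P450 gene outside the cluster, AOL_s00080g313. Its call in the libraries labelled Aovps1 mutant was lost without WT library 1 (adjusted p = 0.0738) or without their library 1, 2 or 3 (0.119, 0.0716 and 0.129). It was also lost there with a replicate block (0.05 after rounding), and in the libraries labelled Aomdv1 mutant when only those 2 groups were fitted (0.0635).

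For ER processing 23 of 112 genes rose and 2 fell (37 and 4 over the list alone; camera adjusted p = 0.000648, and 0.946 with an estimated correlation). With median-ratio scaling 9 rose and 4 fell, and with quantile scaling 15 and 4. GO terms for protein folding (19 of 79, adjusted p = 0.00791) and the Golgi stack (8 of 14, adjusted p = 0.00191) were enriched among risers. The ER chaperone calnexin (AOL_s00078g160) rose from 155.1 ± 20.9 to 365.3 ± 34.2 FPKM (1.24, adjusted p = 0.00712) and HSP16 (AOL_s00097g499) from 21.50 ± 6.34 to 1254 ± 152 (5.83, adjusted p = 2.26e-06). Autophagy had 16 risers and 1 faller of 102 (21 and 1 over the list alone; 9 and 1 with median-ratio and 10 and 0 with quantile scaling). Its camera adjusted p was 0.00428, but 0.0542 without WT library 3 and 0.946 with an estimated correlation, with Atg3 (AOL_s00078g458) at 104.1 ± 5.87 FPKM (1.83, adjusted p = 0.00197). In mitophagy 2 of 49 rose and 0 fell (1 and 0 over the list alone; camera adjusted p = 0.433), and in oxidative phosphorylation 1 of 97 rose and 1 fell, with the same numbers over the list alone (camera adjusted p = 0.708).

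Surface, secretion and spore lists held risers and fallers and were not shifted as sets. Adhesion, lectin and CFEM proteins had 9 up and 13 down of 82 (14 and 16 over the list alone; camera adjusted p = 0.219), and chitin and cell wall 17 up and 20 down of 192 (21 and 22 over the list alone; 0.397). Their median log2 fold changes of 0.10 and 0.19 were positive, but below the 0.304 of all genes, so camera gave both as down. Both medians turned negative with quantile scaling (-0.037 and -0.035) and with median-ratio scaling (-0.235 and -0.185). MFS transporters, 13 up and 11 down of 122 (18 and 16 over the list alone; 0.237), turned to 5 up and 17 down with median-ratio and 10 up and 15 down with quantile scaling. Conidiation and velvet regulators had 1 up and 2 down of 35 under both adjustments (0.397), with fluG (AOL_s00043g361) at 26.55 ± 3.37 FPKM (2.62, adjusted p = 0.00127). The cuticle-degrading protease gene AOL_s00075g8 fell to 0.793 ± 0.471 FPKM (-3.42, adjusted p = 0.000305), the LysM gene AOL_s00006g493 to 5.19 ± 1.71 (-3.82, adjusted p = 9.46e-05) and the carboxykinase gene AOL_s00004g362 to 319.0 ± 129.5 (-2.69, adjusted p = 0.00479). Catalase B (AOL_s00076g488) rose to 21.78 ± 5.18 FPKM (4.17, adjusted p = 9.57e-05) and the nitrate reductase gene AOL_s00210g163 to 25.27 ± 5.73 (2.64, adjusted p = 0.00132). Among fallers the extracellular region (33 of 255, 11.25 expected, adjusted p = 3.07e-05) and tyrosine metabolism (10 of 45, adjusted p = 0.000122) were enriched.

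In all, 1426 genes passed, 888 up and 538 down, 1370 of them with at least a 2-fold change. At an unadjusted p under 0.05 there were 3146, and in 4742 (46%, against 10% by chance) the groups did not overlap. The median log2 fold change of all genes was 0.304, and -0.04 with median-ratio and 0.09 with quantile scaling. The rising share of 62.3% accordingly became 38.9% (500 and 784) and 49.5% (671 and 685). It was 74.3% (1576 and 546) without WT library 3. The count was 839 and 586 without WT libraries 1 and 2, and 677, 704 and 626 without libraries 1, 2 and 3 labelled Aovps1 mutant. A fit of only the 2 groups compared, whose spread leaves out the libraries labelled Aomdv1 mutant, gave 2463. The 4 list calls were not made with an estimated correlation (adjusted p = 0.946 with an estimated correlation).

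**Figure D3:**
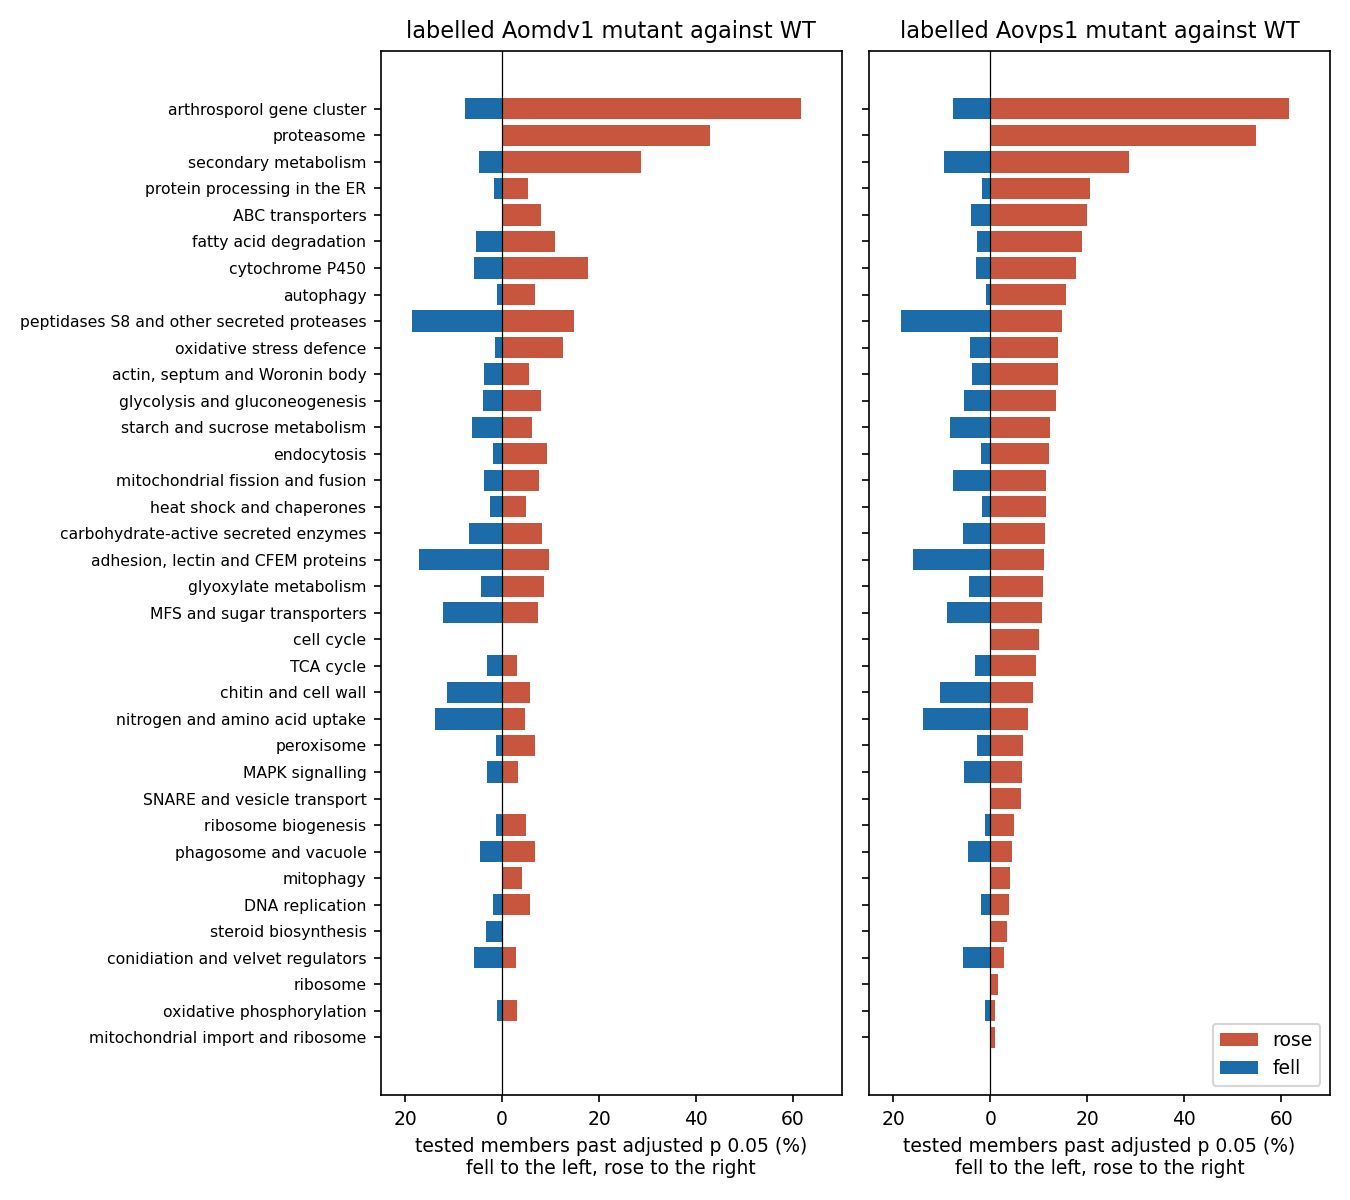
Share of tested genes past an adjusted p of 0.05 (x axis, percent; fell in blue to the left, rose in red to the right) for the 36 gene lists, in the libraries labelled Aomdv1 mutant and Aovps1 mutant against WT. The proteasome (18 and 23 of 42 rose) and the arthrosporol cluster (8 of 13 rose in each) reach furthest to the right; with median-ratio scaling the balance turns from more up to more down for DNA replication and carbohydrate-active secreted enzymes in both, for actin, heat shock, oxidative phosphorylation and phagosome in the libraries labelled Aomdv1 mutant, and for MFS transporters, MAPK signalling, oxidative stress defence, starch and sucrose, glyoxylate, peroxisome, ribosome biogenesis and steroid biosynthesis in those labelled Aovps1 mutant.

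The comparison of the mutants with each other asks whether loss of the dynamin-related protein and of the adaptor act apart. Single genes gave no answer in the main fit: 0 passed the threshold with limma, against 978 at an unadjusted p under 0.05. The smallest adjusted p was 0.0612. Voom also called 0, but array weights called 79 (24 up and 55 down). Leaving out WT library 3 and library 3 labelled Aomdv1 mutant together gave 58 (10 up and 48 down). In 2420 genes (23.5%, against 10% by chance) the groups did not overlap. As sets, genes of the cell cycle (109 tested, median log2 fold change 0.59, camera adjusted p = 5.43e-08) and of DNA replication (52 tested, 0.53, adjusted p = 0.00104) were called as higher in the libraries labelled Aovps1 mutant than in those labelled Aomdv1 mutant. These and all other list calls of this comparison were lost with an estimated correlation (adjusted p = 0.971), and the fold change between the mutants correlated with gene span across genes (Spearman 0.263, against -0.105 and 0.084 for the comparisons with WT). Oxidative phosphorylation (-0.21, adjusted p = 9.91e-05), ribosome biogenesis (-0.15, adjusted p = 0.00285), mitochondrial import and ribosome (-0.08, adjusted p = 0.00488) and the KEGG map of the ribosome (-0.04, adjusted p = 0.00456) stood lower. Without library 3 labelled Aomdv1 mutant the adjusted p was 0.324 for oxidative phosphorylation, 0.105 for ribosome biogenesis and 0.633 for mitochondrial import, while cell cycle, DNA replication and the ribosome still passed. The ribosome call was lost without library 1 labelled Aomdv1 mutant (adjusted p = 0.109) or library 1 labelled Aovps1 mutant (0.391). Mitochondrial import was also lost without library 1 labelled Aomdv1 mutant (0.109) or library 1 or 3 labelled Aovps1 mutant (0.0828 and 0.0666), and ribosome biogenesis without library 1 labelled Aovps1 mutant (0.0937). With quantile scaling the direction of the ribosome turned (0.831), and oxidative phosphorylation (0.251) and mitochondrial import (0.182) were lost. The gene count without library 1 labelled Aomdv1 mutant was 24, and without library 3 of that label 2.

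The 2 mutants changed largely the same genes. Of the 1015 and 1426 genes called, 805 were shared, 454 up in both and 351 down in both, and 0 went opposite ways. Independent lists of these sizes would share 49.9 and 22.7. The shared genes were 79.3% of the calls for the libraries labelled Aomdv1 mutant and 56.5% of those for the libraries labelled Aovps1 mutant. Across the 10318 genes, which are not independent replicates, fold changes correlated at 0.844. Both were computed against the same WT libraries, which alone gave a correlation of 0.467 to 0.53 in 100 simulations of unchanged groups. The 3 WT libraries cannot give 2 to each comparison and were not split, so no comparison free of shared WT libraries was made. Without WT libraries 1, 2 and 3 the shared count was 510, 396 and 1139, and without libraries 1, 2 and 3 labelled Aovps1 mutant 518, 526 and 506. The annotated genes with the largest changes in both were, upward, AOL_s00076g487, AOL_s00215g259, AOL_s00054g302, AOL_s00081g9 and AOL_s00110g290. Downward they were the hydrophobin AOL_s00006g570, the lectin AOL_s00006g511, the pho-4 permease AOL_s00169g251, the elongation factor 2-like gene AOL_s00210g187 and the copper transporter AOL_s00078g476.

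**Figure D4:**
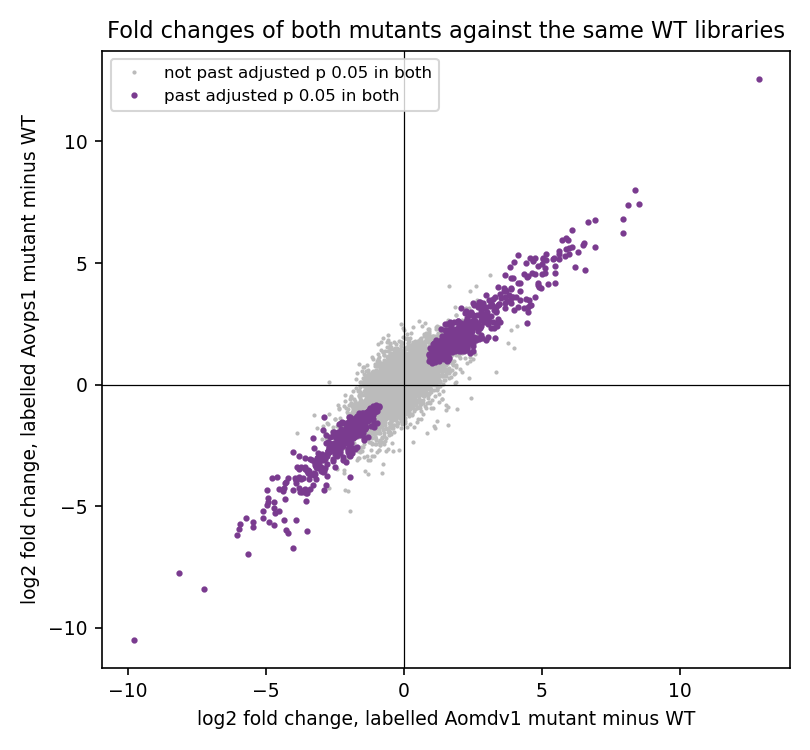
Log2 fold change against WT of 10318 genes in the libraries labelled Aomdv1 mutant (x axis) and Aovps1 mutant (y axis); each point is a gene, purple where it passed an adjusted p of 0.05 in both. The 805 purple points lie in the upper right (454) and lower left (351) and 0 elsewhere; the fold changes share their WT libraries.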

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

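Some tests in this part were chosen only after the result was seen. They are voom, array weights, leaving out 2 libraries together, the levels of abundant mutant transcripts in WT library 3 and the correlations of fold changes with gene span. The results in this part were singled out because a test of the difference between the mutants passed, or, for 10 genes, because the mutants moved to opposite sides of WT.

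By camera, 10 lists differed between the libraries labelled Aovps1 mutant and those labelled Aomdv1 mutant. Higher in the libraries labelled Aovps1 mutant were cell cycle (adjusted p = 5.43e-08), DNA replication (0.00104), actin, septum and Woronin body (0.0101), chitin and cell wall (0.0171) and protein processing in the ER (0.0489). Lower were oxidative phosphorylation (9.91e-05), ribosome biogenesis (0.00285), ribosome (0.00456), mitochondrial import and ribosome (0.00488) and oxidative stress defence (0.0277). With an estimated correlation each had an adjusted p of 0.971, and 0 single genes passed with limma (978 at an unadjusted p under 0.05). Voom called 0 too, while array weights called 79. Leaving out WT library 3 and library 3 labelled Aomdv1 mutant together gave 58. ER processing no longer passed without any one of the 6 mutant libraries (adjusted p = 0.0611, 0.0632 and 0.143 without libraries 1, 2 and 3 labelled Aomdv1 mutant, and 0.0505, 0.0969 and 0.0775 without those labelled Aovps1 mutant). Without library 1 labelled Aovps1 mutant, oxidative stress defence (0.0505), ribosome biogenesis (0.0937), mitochondrial import (0.0828) and the ribosome (0.391) were lost too. Mitochondrial import was also lost without library 3 labelled Aovps1 mutant (0.0666), and it and the ribosome without library 1 labelled Aomdv1 mutant (0.109 each). Quantile scaling ended the calls of oxidative phosphorylation (0.251), oxidative stress defence (0.376) and mitochondrial import (0.182) and turned the direction of the ribosome (0.831).

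In 10 genes every library labelled Aomdv1 mutant lay on one side of every WT library and every library labelled Aovps1 mutant on the other. Above WT in the libraries labelled Aomdv1 mutant were glutaredoxin-2 (AOL_s00006g226, means 244.5 in WT, 512.6 and 196.4 FPKM), the import protein Tim9 (AOL_s00075g196, 309.2, 472.9 and 254.9), AOL_s00097g380 (42.80, 129.8 and 21.3), AOL_s00004g529 and AOL_s00097g492. Below WT there were replication factor A 2 (AOL_s00006g345, 55.21, 39.21 and 69.22), replication factor C 4 (AOL_s00215g564, 35.95, 22.94 and 44.26), squalene synthase (AOL_s00004g98), the repair gene rhp54 (AOL_s00079g379) and AOL_s00004g76. The rule tested no difference, and limma's own test between the mutants gave adjusted p-values of 0.278 to 0.514 for them. The number that chance gives was not computed, so the 10 genes do not show that the mutants move apart.

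The list differences can be weighed against the state of 2 libraries, since WT library 3 and library 3 labelled Aomdv1 mutant stand apart from the others of their groups. Among 2976 genes at a mean of 50 FPKM or more, the best correlation of each with its group was 0.819 and 0.744 where the other 2 libraries reached 0.97 and 0.891 (differences of -0.151 and -0.147), so counting noise at low depth is not the cause. Admixed RNA of the other genotype is argued against in both: the deviation of library 3 labelled Aomdv1 mutant correlated at 0.055 with the difference between genotypes, and in WT library 3, where that correlation left the question undecided (0.262), 17 transcripts abundant in both mutants and low in WT libraries 1 and 2 stood at a median of 1.6% of the lower mutant mean (AOL_s00076g487 at 0.0053%). Loss of long transcripts may contribute in library 3 labelled Aomdv1 mutant, whose deviation correlated with gene span at -0.313 (Spearman, across genes), past the bound set beforehand, and stays open for WT library 3 (-0.203); no biological explanation was tested. Across all genes the fold change between the mutants also correlated with gene span (0.263, against -0.105 and 0.084 for the libraries labelled Aomdv1 and Aovps1 mutant against WT), so transcript recovery stays open for the list differences.

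Without library 3 labelled Aomdv1 mutant, 7 of the 10 lists were no longer called, and the medians given are log2 fold changes of the list minus that of all genes, with all libraries and without that one. For oxidative phosphorylation (-0.37 and -0.10, adjusted p = 0.324), oxidative stress defence (-0.29 and -0.07, 0.515), mitochondrial import (-0.24 and -0.07, 0.633) and chitin and cell wall (0.20 and 0.09, 0.324) the median moved toward 0. So it did for ribosome biogenesis (-0.31 and -0.20, 0.105) and actin (0.23 and 0.13, 0.105). For ER processing it stayed (0.13 and 0.13, 0.143), a call that was lost without each of the other mutant libraries too. Cell cycle (0.42 and 0.21, 0.0003), DNA replication (0.37 and 0.41, 1.4e-05) and ribosome (-0.20 and -0.22, 0.013) were still called.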

How the results depend on the processing

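Leaving both outlying libraries out, array weights, voom, lists without KEGG ortholog names and both mutants together against WT were chosen only after the result was seen. The planned count-based tests were not run, since only FPKM values were at hand. Of 210 results for single named genes, some of which could not be tested in every alternative, 51 lost their call in at least 1, 159 lost none and 0 reversed. They include the partner genes of fission and fusion, of which FZO1 (AOL_s00054g413) in the libraries labelled Aovps1 mutant was called only with array weights and without both outlying libraries. Calls were lost in 40 and 32 of 198 without WT libraries 2 and 1, 21 of 109 without each library labelled Aovps1 mutant, and 24 of 210 in fits of only the 2 groups compared. Pseudocount 0.1 (967, 1377 and 0 genes for the 3 comparisons), voom (906, 1357 and 0), the stricter filter and quantile scaling left the gene counts within 1.5 times. Where no reason is given, the cause was not tested.

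For the libraries labelled Aomdv1 mutant (1015 genes, 993 at 2-fold), leaving both outlying libraries out gave 2631 (1988) and array weights 2572 (2092). A fit of only those 2 groups lowered the count to 528 (528), while the same kind of fit raised it for the label Aovps1 mutant. All 528 were among the 1015 of the main fit. The main fit took the spread of each gene from all 3 groups, so each count also depends on libraries outside its comparison. Leaving out single libraries gave 515 to 1392 (515 to 1351 at 2-fold). For those labelled Aovps1 mutant (1426, 1370), both outlying libraries out gave 4378 (2862), array weights 5209 (2990) and the fit of 2 groups 2463, and single libraries 586 to 2122 (586 to 1976). Between the mutants (0), no filter and median-ratio scaling gave 1, both outlying libraries out 58, array weights 79 (77 at 2-fold) and single libraries 0 to 24, the highest without library 1 labelled Aomdv1 mutant. The overlap (805) became 2292 without both outlying libraries and 2406 with array weights, and 396 to 1139 without single libraries.

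List calls for the libraries labelled Aomdv1 mutant (12) became 4 with quantile scaling, 5 without both outlying libraries, 0 with an estimated correlation and 5 to 15 without single libraries (5 without library 3 of that label, 6 without WT library 3). For those labelled Aovps1 mutant (4) they became 8 with no filter, 0 with an estimated correlation and 4 to 6 without single libraries; between the mutants (10) they became 5 without both outlying libraries, 0 with an estimated correlation and 5 to 12. Enriched terms (19 and 37) became 64 and 59 without both outlying libraries and 50 and 96 with array weights, and 19 with median-ratio scaling for the libraries labelled Aovps1 mutant; without single libraries they were 19 to 40 and 11 to 41.

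VPS1 (AOL_s00007g394) in the libraries labelled Aovps1 mutant had a log2 fold change of -1.23 with a replicate block (adjusted p = 0.0653), and -1.41 to -0.90 without single libraries (0.0508 to 0.159); the remaining alternatives kept it past the threshold (0.00712 to 0.0462). In the libraries labelled Aomdv1 mutant VPS1 ranged from -1.14 to -0.83 without single libraries. MDV1 (AOL_s00097g206) without single libraries ranged from -0.29 to 0.02 in the libraries labelled Aomdv1 mutant and from -0.13 to 0.12 in those labelled Aovps1 mutant. With quantile and median-ratio scaling it was -0.38 and -0.36, and -0.19 and -0.37, and it passed the threshold in 0 alternatives.

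Replicate numbers do not pair the samples: 1 of 9 libraries correlated best with its own number in both other groups, after group means were removed. With a replicate block 894, 1178 and 0 genes passed and 703 were shared. The depth of 15850000 to 19300000 fragments limits genes near FPKM 1, which stand for 21.6 to 26.3 fragments at the median gene span.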

Other observations

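The tests of swapped labels, of another deleted gene, of a partial knockdown, of WT library 3 alone and of phosphate genes were chosen only after the result was seen, as were the splits of both mutants together; the remaining tests in this part were set before.

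Genes that changed together often lay side by side on the scaffolds. Among genes called in both mutants there were 10 runs of 3 or more adjacent risers (longest 4) and 4 runs of adjacent fallers (longest 5). The longest was AOL_s00007g55 to AOL_s00007g59 (NW_011645564.1, 157692 to 167933), which fell and includes the methionine permease AOL_s00007g56. Runs of risers were AOL_s00054g648 to g651, AOL_s00110g45 to g48, AOL_s00169g76 to g79 and, in the arthrosporol region, AOL_s00215g273 to g276 and g280 to g283. Among the genes that rose in the libraries labelled Aomdv1 mutant 74 pairs were direct neighbours, against a mean of 26.9 and at most 44 in 1000 random draws; 39 of the pairs lay over 1 kb apart and 0 overlapped. Fallers in the same libraries made 64 pairs (15.2 by chance, at most 27), and risers and fallers in the libraries labelled Aovps1 mutant 137 (67, at most 93) and 73 (20.5, at most 36). Physical clusters of co-regulated genes are a candidate explanation. The draws measure only the adjacency itself, so they cannot tell this explanation from another source of it.

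4 genes of phosphate supply fell in both mutants: the pho-4 permease AOL_s00169g251, the phytase AOL_s00169g232 (means 39.68 in WT, 0.09 and 0.167 FPKM), the alkaline phosphatase AOL_s00215g838 (261.6, 7.58 and 9.51) and the glycerophosphoinositol permease GIT3 (AOL_s00076g624, 44.33, 2.69 and 2.92). Some other genes of these kinds were not called in either mutant. They include a second pho-4 permease (AOL_s00075g117, 1.94, 2.19 and 2.22), a repressible alkaline phosphatase (AOL_s00004g413, 60.48, 53.74 and 59.15) and a 3-phytase (AOL_s00170g3, 19.25, 18.98 and 30.97). Whether a wider phosphate programme is higher in WT was tested on 22 genes found by keywords for phosphate, the 4 genes named first left out. The keywords also took in genes of other functions, such as triose-phosphate transporters and a phosphotyrosine protein phosphatase. Against 10000 random lists their medians of -0.3 and -0.067 (labelled Aomdv1 and Aovps1 mutant) lay at percentiles of 0.48 and 0.94 (on a scale to 100), low enough for the bound first set. Their members went both ways, 7 above 0 and 15 below in the libraries labelled Aomdv1 mutant and 10 above and 12 below in those labelled Aovps1 mutant, and few passed the threshold (0 rose and 1 fell, and 1 rose and 2 fell). Among the fallers was AOL_s00170g4, annotated with an esterase-like phytase domain, which fell in both mutants. Its log2 fold changes were -2.08 (limma adjusted p = 0.00341) and -1.79 (0.00744). A fall of the wider list therefore stays open. The phosphate content of the plates was not measured.

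The targeted genes kept transcript signal in the libraries labelled as their mutants. If the strains were full deletions, a swap of labels among the 9 libraries would leave some of them without the transcript, but the lowest library reached 70.6% of the median for MDV1 and 48.1% for VPS1, which argues against it. A swap among partial knockdowns stays open. Deletion of another listed gene in a single mutant is also argued against. For genes at 5 FPKM or more in the other 6 libraries, 0 were lost in all 3 libraries of one mutant. Those 6 libraries include the ones of the other mutant, so the test could not find a gene lost in both mutants. Deletion of a gene in both mutants therefore stays open, as does that of a gene below this level. A partial knockdown of VPS1 in the libraries labelled Aovps1 mutant cannot be told apart from a fall in both mutants, as the difference between them was -0.26 on the log2 scale with an interval on both sides of 0. A deletion that leaves part of a transcript could not be tested without reads, and no test here shows the genotypes.

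That both mutants change the same genes may come in part from their shared WT libraries. The covariance of the fold changes was 0.975 against 0.094 to 0.115 in the simulated unchanged groups, which argues against the shared libraries as the whole source. WT library 3, which stands apart, is not the source either, since 1139 genes were shared without it. The batch tag of the labels holds a culture day, which all 9 libraries share, and no processing batch is given. A batch or culture difference between WT and mutants was therefore not tested. A common effect of losing either protein stays among the open explanations, untested.

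Other splits of the libraries were counted for each comparison, in fits of only those libraries over the 10318 genes kept with all 9. The counts therefore differ from the 528 and 2463 of fits in which the filter was applied to the 6 libraries alone. For 3 against 3 libraries the 10 splits are too few for a share under 0.05: the real split gave 508 genes for the libraries labelled Aomdv1 mutant and 2483 for those labelled Aovps1 mutant, each in 1 split, with a highest other of 0, and the split between the mutants gave 0 as did the others (10 of 10). With both mutants together against WT, 1 of 84 splits gave as many genes as the real 1544, and the highest other gave 65. A chance split of the libraries is therefore an unlikely source there. The splits cannot tell genotype from a batch or culture difference between WT and mutants.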
